A study of Mus musculus with 6 samples.

How the data were processed

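Messenger RNA was measured on 4 CodeLink Mouse Whole Genome arrays of 1 colour (Cy5), per the labels' protocols and the series' design text. There were 2 litters, and incisors of wild types and mutants of a litter were pooled per genotype before RNA extraction. miRNAs were measured by a service provider on 2 arrays stained with Cy3, per the labels' protocols. There, small RNAs from 4 to 8 µg of total RNA were isolated by size and received a poly(A) tail and a tag before staining. The deposited mRNA files give spot intensity and local background intensity, and their background-subtracted intensity is the mean of the spot less the median background, as was checked on each unmasked spot. The deposited miRNA files give the mean spot intensity with no background column, and empty spots had median intensities of 207 (ameloblast array) and 345 (cervical loop array). Scanners and software versions are not given in the sources used here.

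The deposited value tables were used as an alternative. For the mRNA arrays the table holds the background-subtracted intensity divided by 1 constant per array, with column medians of 1.03, 1.06, 1.04 and 1.06 (wild type 1 and 2, mutant 1 and 2). In the columns of wild type 1 and mutant 1, 1108 and 1100 of 1260 spots of repeated probes hold other values than the scanner file at the same position (tolerance 0.1 percent), and no spot of a probe spotted once does. For the miRNA arrays the table holds intensities that follow the raw means (Spearman correlations over miRNAs of 0.978 and 0.936), with column medians of 29 and 27, and how it was scaled stays unknown.

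For the mRNA arrays, spot and background intensities were corrected with normexp and an offset of 50, quantile normalized between arrays and put on the log2 scale. Masked, contaminated, irregular or excluded spots were set aside, and dim and saturated spots were kept. The 94 probes with 10 to 20 spots each were treated as controls and left out, which left 34967 probes. A probe was tested if the scanner marked it as above background on both arrays of at least 1 genotype. The median background was 66 and 57 on the wild-type arrays and 71 and 56 on the mutant arrays, and the median background-subtracted intensity was 85.4, 86.4, 107.3 and 133.1 in the same order. Genotypes were compared with limma (lmFit and eBayes) with genotype as the only factor and Benjamini-Hochberg adjustment. Nothing in the labels says more of a pool than its genotype, number and the 3 to 5 mice in it. The p-values rest on the spread between these pools, which eBayes moderates for each probe with the spread over all probes.

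The alternative fit holds the replicate number as a block. It leaves few residual degrees of freedom per probe. Its standard errors and p-values therefore lean on the spread that eBayes shares over probes. The design text says that mutants and wild types were dissected from the same litter and that 2 litters were used. No sentence of the labels or the design text ties the numbers to the litters, so that the numbers are litters is an assumption. Arrays of the same number also carry neighbouring array identifiers per the file names, and a run of arrays shared by number cannot be told apart from the litter. The deviations of same-numbered arrays from their genotype means correlated at 0.876 over probes.

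On simulated arrays with the litter differences of these data, 200 probes were changed by each of 3 sizes among the 21274 tested probes with values on all 4 arrays. The fit on genotype alone recovered 0 percent of the probes changed by 1, 2 or 4 on the log2 scale, with 0 false calls. The fit with the litter as a block recovered 0 percent, 45.0 percent and 74.5 percent of them, with 2 false calls. The noise was drawn independently for each probe. Its SDs came from the differences between the 2 litter pairs, shuffled over probes. Blocked calls on the real arrays had median log2 changes of 1.20 (higher) and 1.36 (lower), a size that the simulation seldom recovered. These shares therefore give neither the power nor the false-call rate on the real arrays.

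The files and tables used here do not pair the mRNA probe numbers with genes. The tests of Dicer1, Nog and Pitx2, of the gene lists and of miRNA seed matches were therefore not run, and the labels of the mutant arrays could not be checked through Dicer1. By the rule fixed before the data were examined, the named probes are those of largest fold change among probes whose mutant arrays both lie beyond both wild-type arrays. As no probe passed the threshold without the block, the rule fills the list by fold change. Because the probes have no gene names here, only the first 2 per direction are named, fewer than the rule asks for.

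For the miRNA arrays, intensities were corrected with normexp and an offset of 50, quantile normalized over the 3500 spots of 700 mouse miRNAs and averaged over 5 repeat spots on the log2 scale. A miRNA was called above background where its mean raw intensity and at least 3 of its spots exceeded a threshold of 216.0 (ameloblast array) or 402.7 (cervical loop array), set at the mode of the dim miRNAs plus 3 times the spread below it. On this basis 300 miRNAs were above background on the ameloblast array and 175 on the cervical loop array. The median SD of repeat spots was 0.11 and 0.27 on the log2 scale. This definition was chosen after the raw intensities had been seen. Named miRNAs are the members of lists fixed before the data were examined and up to 10 per direction with a log2 ratio of at least 1 in size. Each list with at least 3 members above background was set against 10000 random lists of the same size matched on mean signal in 5 bins. On simulated ratios a list of 5 shifted by 1 lay at percentile 99.95, and 5 percent of 200 unshifted lists lay outside the central 95 percent. The unshifted lists were drawn at random without matching on signal. They therefore do not check the percentiles of lists whose members share a gene cluster or sequence. Neighbouring miRNA genes were read from the RefSeq annotation of GRCm38.p6.

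R 4.3.3 with limma 3.58.1 and Python 3.11.15 with matplotlib 3.10.9 were used. Alternatives were other background corrections, scalings, filters, sources of the values and summaries of repeat spots, the litter block, other prior variances and leaving out each mRNA array.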

Results

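The data came from lower incisors of newborn mice, a tooth that grows throughout life. Epithelial stem cells in the labial cervical loop, at the growing end of this tooth, give rise to pre-ameloblasts and then to ameloblasts, the cells that secrete enamel. MicroRNAs (miRNAs) were measured in wild-type incisors in dissected labial cervical loop cells and in the dissected region of pre-ameloblasts and ameloblasts, with 1 array per region. Messenger RNA was measured in whole lower incisors of wild-type mice and of conditional mutants that lost Dicer1, the enzyme that cuts precursor hairpins into mature miRNAs, in cells with Pitx2-Cre activity, which includes the dental epithelium. Each genotype had 2 arrays, each made from pooled incisors of 3 to 5 mice, and the pools of the 2 genotypes came from the same 2 litters. The replicate numbers 1 and 2 were taken as the litters, a link that the labels do not state. The number of arrays limits the precision of every value given here.

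The first comparison asked which miRNAs differ in level between the ameloblast region and the cervical loop. After quantile normalization, miR-200b, miR-200c and miR-429 of the miR-200 family, which is abundant in epithelia and represses Zeb1 and Zeb2, were brighter on the ameloblast array. The normalized log2 signal of miR-200c (UAAUACUGCCGGGUAAUGAUGGA) was 12.08 ± 0.05 on the ameloblast array and 11.04 ± 0.12 on the cervical loop array, where ± is the SD over 5 repeat spots and covers technical error within an array only. The difference was 1.04 on the log2 scale, or 2.06-fold. For miR-200b (UAAUACUGCCUGGUAAUGAUGA) the signals were 9.42 ± 0.10 and 7.74 ± 0.33, a difference of 1.67 or 3.19-fold. With scaling to the 75th percentile of the miRNAs detected on both arrays the differences were 0.59 for miR-200c and 0.87 for miR-200b, and with that of all miRNA probes they were 2.23 and 2.51. For miR-429, which shares bases 2 to 8 (AAUACUG) with miR-200b and miR-200c, the difference was 0.93, and -0.22 with scaling to the 75th percentile of the miRNAs detected on both arrays. miR-200a was above background on the ameloblast array only and its signal allowed no bound on the fold. miR-141, whose gene stands next to that of miR-200c in the mouse annotation, was not above background on either array, so its ratio between the regions was not detectable. The median log2 ratio of the 4 family members above background was 0.98 and lay at percentile 100 of 10000 random lists matched on mean signal. Here and below, the random lists draw miRNAs independently, while list members can share a gene cluster or sequence. The percentiles can therefore overstate how unusual a list is. The family median was 0.18 with scaling to the 75th percentile of the miRNAs detected on both arrays and 2.40 with the empty spots as background. The empty-spot setting floors dim signals at a low value, and there the list of muscle miRNAs had a higher median of 2.95. The value of 2.40 is therefore not particular to this family. As each region had 1 array, the differences between regions have no replicate check and no p-value.

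**Figure D1:**
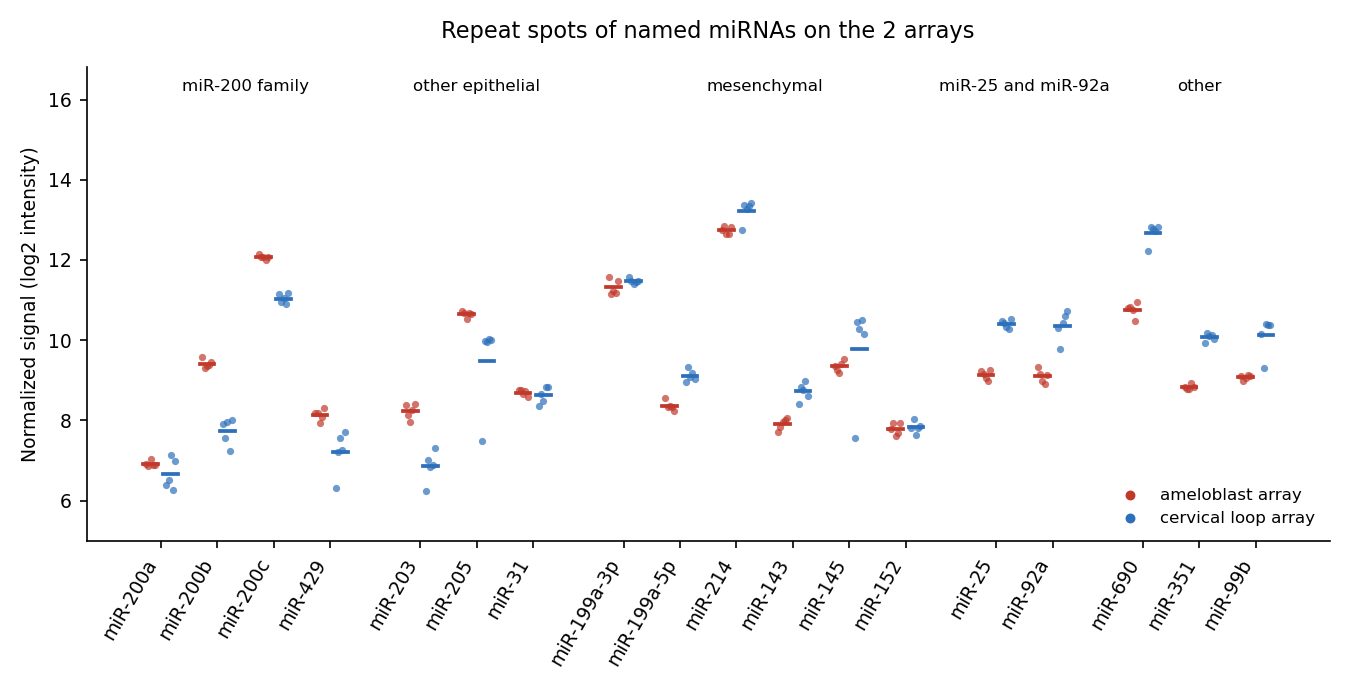
Normalized signal (log2 intensity) of the repeat spots of named miRNAs on the ameloblast array (red) and the cervical loop array (blue), with 5 spots per miRNA and array as points and their mean as a line. The miR-200c spots average 12.08 on the ameloblast array and 11.04 on the cervical loop array, while those of miR-25 average 9.14 and 10.41, a difference whose sign turns with scaling to the 75th percentile of all miRNA probes.

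Other epithelial miRNAs were unequal in their ratios. miR-203, which promotes epidermal differentiation by repressing p63, was above background on the ameloblast array only and was at least 2.35-fold higher there after quantile normalization. Its log2 ratio was 0.75 without background correction and 0.08 with scaling to the 75th percentile of the miRNAs detected on both arrays. Here and below, such a bound sets the brighter signal against the higher of the dim signal and the lowest signal among detected miRNAs. miR-205, another epithelial miRNA, had signals of 10.66 ± 0.08 and 9.49 ± 1.12 and a log2 ratio of 1.17, which was 0.70 with the median of the repeat spots. The ratio of miR-31 was 0.06, less than the spread of 0.22 between its spots. The median of these 3 miRNAs was 1.17, at percentile 99.6 of the matched random lists, and with the median of repeat spots it was 0.70, at percentile 98.6. It was 0.08 with scaling to the 75th percentile of the miRNAs detected on both arrays and 1.72 with that of all miRNA probes. Over the 2 members above background on both arrays it was 0.61. Of the miR-183 cluster, which serves sensory epithelia, miR-182 and miR-183 were above background and had ratios of 0.15 and 0.05.

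The 6 members of the mesenchymal list above background had a median log2 ratio of -0.46, at percentile 1.33 of the random lists, which turned to 0.70 with scaling to the 75th percentile of all miRNA probes and to 0.44 with scaling to the 5S rRNA probes. The ratio was -0.81 for miR-143 and -0.75 for miR-199a-5p, both larger than the spread between spots, which was 0.26 and 0.18, and the latter turned to 0.21 with scaling to the 75th percentile of all miRNA probes. For miR-214, which is transcribed with miR-199a, it was -0.49 against a spread of 0.29. For miR-145, the partner of miR-143, it was -0.44 with the mean of its spots and -0.91 with their median, and the signs of miR-214 and miR-145 turned with the same 2 scalings as that of the list. miR-199a-3p and miR-152 had ratios of -0.15 and -0.04, within the spread between their spots, and also changed sign with cyclic loess.

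**Figure D2:**
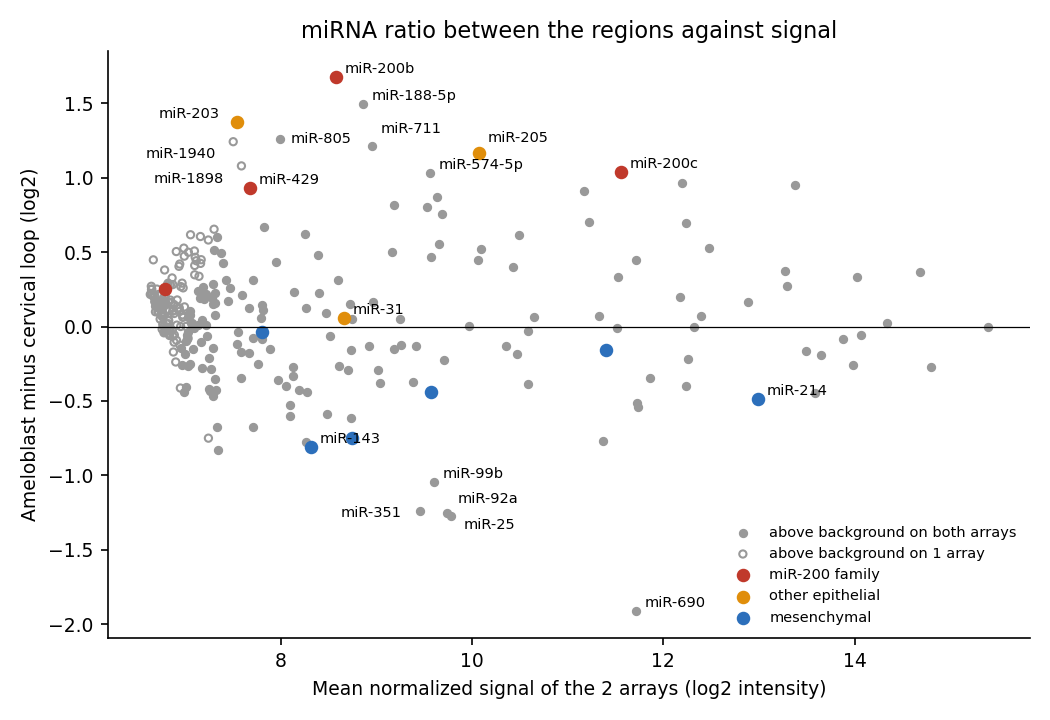
Log2 ratio of ameloblast over cervical loop signal against the mean normalized signal (log2 intensity) for the 301 miRNAs above background on at least 1 array, with the fixed lists in colour. The highest ratio among named miRNAs is 1.67 for miR-200b and the lowest is -1.91 for miR-690; other scalings move the points by unequal amounts and turn the signs of some of them.

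Among the 150 miRNAs above background whose brighter array lay above the median of detected miRNAs, 10 were at least 2-fold brighter on the ameloblast array and 5 on the cervical loop array. These counts were 0 and 52 with scaling to the 75th percentile of the miRNAs detected on both arrays, 56 and 0 with that of all miRNA probes and 42 and 1 with scaling to the 5S rRNA probes. Besides miR-200b, miR-200c, miR-203 and miR-205, the former were miR-188-5p (log2 ratio 1.49), miR-805 (1.26), miR-1940, miR-711, miR-1898 and miR-574-5p (1.03). miR-1940 and miR-1898 were above background on the ameloblast array only and were at least 2.18-fold and 2.11-fold higher there, with signs that turned with scaling to the 75th percentile of the miRNAs detected on both arrays. For miR-711 the ratio of 1.22 rested on the mean of unequal spots (SD 2.40 on the ameloblast array) and was 0.21 with their median. For miR-574-5p the ratio was smaller than the spread between its spots of 1.25 and was 0.73 with their median. Brighter on the cervical loop array were miR-690, with a log2 ratio of -1.91 and signals of 10.76 ± 0.18 and 12.67 ± 0.25, miR-25 (-1.27), miR-92a (-1.26), miR-351 (-1.24) and miR-99b (-1.05), and of these the ratios of miR-25, miR-92a, miR-351 and miR-99b turned to small positive values with scaling to the 75th percentile of all miRNA probes. miR-25 (CAUUGCACUUGUCUCGGUCUGA) and miR-92a (UAUUGCACUUGUCCCGGCCUG) share bases 2 to 8 (AUUGCAC) and belong to the miR-17-92 cluster and its paralogs, which promote proliferation. The other 7 members of these clusters above background had smaller ratios, and the median of all 9 was -0.15 at percentile 5.9, or -0.48 at percentile 0.1 with the median of repeat spots. The 9 let-7 family members, which accumulate as cells differentiate, had a median ratio of 0.16 at percentile 70.2, and let-7a moved from 0.96 to 0.29 with the median of its spots.

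In the remaining lists with at least 3 members above background, the median ratio was 0.27 for muscle miRNAs (percentile 91.9), 0.20 for the miR-23-27-24 clusters (percentile 71.0) and -0.18 for the miR-30 family (percentile 20.1). Of the muscle list, miR-133a and miR-133b were above background on the ameloblast array only and allowed no bound on the fold. Its member above background on both arrays, miR-206, had a ratio of 0.05. Relative to the median of all miRNAs detected on both arrays, these 3 lists, the let-7 family and the miR-17-92 clusters changed sign over the settings tried. Markers of other cell types that the dissections could hold were also measured. The erythroid miR-451 was above background on the cervical loop array only and miR-486 had a ratio of -0.14. The endothelial miR-126-3p had a ratio of 0.87, which was 0.02 with the median of its spots. Of the leukocyte list, miR-223 and miR-150 were above background on the ameloblast array only. Of the neural list, miR-128 had a ratio of 0.01 and miR-138 was above background on the ameloblast array only. Of the miR-34 family, only miR-34a was above background, on the ameloblast array, and no member of the miR-29 family was above background on either array. Several of these calls lie at the thresholds of 216.0 (ameloblast array) and 402.7 (cervical loop array). Raw intensities on the ameloblast array were 218.1 for miR-223, 217.1 for miR-150 and 215.9 for miR-451. The signals of miR-223, miR-150 and miR-34a allowed no bound on the fold. Calls on 1 array only are therefore no evidence of which cells a dissection held.

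The ratios between regions depend on what the arrays are scaled to. The median log2 ratio of the 174 miRNAs above background on both arrays was -0.01 after quantile normalization, -0.96 with scaling to the 75th percentile of the miRNAs detected on both arrays and 0.68 with scaling to the 75th percentile of all miRNA probes. Relative to that median, the miR-200 family lay higher by 0.75 to 2.26 and the other epithelial list by 0.62 to 1.26 over 11 settings, of which the 75th percentile and 5S scalings differ by a constant and give 1 set of relative values. The 2.26 came with the empty spots as background, where the muscle list lay higher by 2.80. Relative to the same median, miR-690, miR-25, miR-92a, miR-351, miR-99b, miR-143 and miR-199a-5p lay lower in each of these settings, where the filter on both arrays leaves the ratios of single miRNAs as they were, and the mesenchymal list lay between -0.59 and 0.02. On the cervical loop array, 9 of 29 bright spots in rows 1 to 16 had less than 50 percent of the median signal of their repeats, against 0 of 156 in the other rows.

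**Figure D3:**
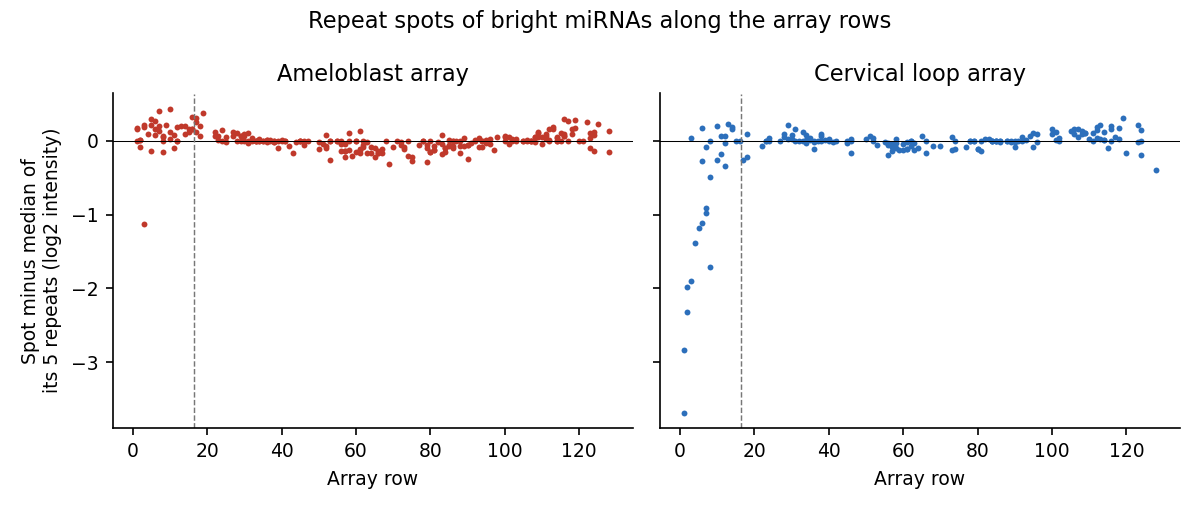
Deviation of each spot (log2 intensity) from the median of the 5 repeats of its miRNA along the rows of the ameloblast and cervical loop arrays, for miRNAs with a median raw signal above 1500. The lowest spot in the first rows of the cervical loop array deviates by -3.68, and the dashed line marks the end of row 16.

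The second comparison asked which transcripts of the whole lower incisor differ between Dicer1 mutants and their wild-type litter mates. The arrays identify transcripts by probe numbers that the tables used here do not pair with genes, so Dicer1, Nog, Pitx2 and the gene lists could not be read from them. With limma and genotype as the only factor, 0 of 21772 probes were higher and 0 were lower in the mutant at an adjusted p below 0.05, and 108 were higher and 227 lower at an unadjusted p below 0.05. With the replicate number, taken as the litter, as a block, 197 probes were higher and 263 were lower in the mutant. The median fold among these was 2.30 for the higher and 2.57 for the lower ones. Arrays of the same litter resembled each other more than arrays of the same genotype, with Pearson correlations over probes of 0.963 and 0.965 within litters against 0.854 between the wild types and 0.868 between the mutants (probes are not independent replicates). Without mutant replicate 1 or mutant replicate 2, the fit on genotype alone called 10 and 5 lower probes.

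The largest differences between genotypes were falls in both litter pairs. Probe GE136327 had a log2 signal of 14.64 ± 0.28 (SD, n = 2) in wild types and 7.20 ± 0.87 (SD, n = 2) in mutants, where it was above background on 1 of 2 arrays, so that it was at least 173-fold lower on average. Its log2 change was thus -7.44 or lower (limma on these signals with the litter as a block, SE 0.23, adjusted p = 2.86e-05). In limma without the block the adjusted p was 0.319. With the block, SEs and p-values draw on the spread over all probes. For a single probe the SE can be smaller or larger than the spread between its 2 litter pairs gives. The change of GE136327 was -6.82 without mutant replicate 2 and -8.05 without mutant replicate 1. As the probe was above background on 1 mutant array, only 1 of these 2 values is a bound. With both mutant arrays its change was -8.25 or lower with the scanner's own background and -8.72 or lower with the deposited values. Probe GE1516177 was saturated on both wild-type arrays and was on average at least 102-fold lower in the mutants, with a log2 change of -6.68 or lower (limma on the saturated signals with the block, adjusted p = 1.05e-04; without it, adjusted p = 0.403). Its wild-type signal being saturated, the change was also -6.06 or lower and -7.29 or lower in the litters 1 and 2, -6.04 or lower without mutant replicate 2 and -7.32 or lower without mutant replicate 1. The largest rise with no overlap between the genotypes was that of probe GE36343, with log2 signals of 7.59 ± 0.36 (SD, n = 2) in wild types and 10.43 ± 0.25 (SD, n = 2) in mutants, a 7.13-fold difference (limma with the block, adjusted p = 5.47e-04; without it, adjusted p = 1.00). Probe GE40505 was 5.22-fold higher in mutants, by 3.07 and 1.69 on the log2 scale in the litters 1 and 2 (limma with the block, adjusted p = 0.0122; without it, adjusted p = 1.00). Over the alternatives run in limma, the adjusted p went from 2.86e-05 to 0.902 for GE136327, from 1.05e-04 to 0.922 for GE1516177, from 5.47e-04 to 1.00 for GE36343 and from 0.0122 to 1.00 for GE40505.

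**Figure D4:**
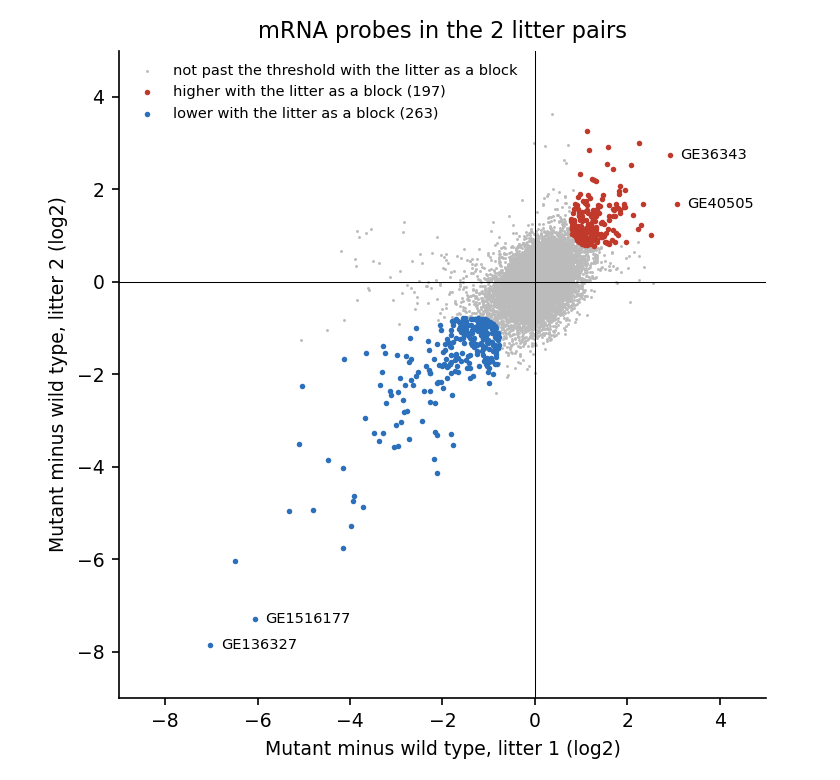
Log2 difference of mutant minus wild type for each mRNA probe tested, in the litter 1 pair (horizontal axis) and the litter 2 pair (vertical axis). Coloured points are the 197 higher and 263 lower probes at an adjusted p below 0.05 with the litter as a block; the 4 labelled probes are those named in the text.

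In both litter pairs, 95 probes were at least 2-fold higher and 173 at least 2-fold lower in the mutant, and 5 were at least 2-fold higher in 1 pair and lower in the other. At 8-fold or more, 18 probes were lower and 0 were higher in both pairs. These counts were 28 and 1 with the scanner's own background and 31 and 1 with the deposited values. The differences between mutant and wild type in the 2 pairs correlated at r = 0.516 over probes. More probes were above background on the mutant arrays, with 67.7 ± 1.54 percent (SD, n = 2) against 60.9 ± 0.342 percent (SD, n = 2) on the wild-type arrays, and 2 arrays against 2 allow no p below 0.333 in a two-sided exact permutation test, the value found. On both mutant arrays and on neither wild-type array, 570 probes were above background, and 47 showed the opposite. The calls with the litter as a block depended on the scaling between arrays, since with median scaling in place of quantile normalization 1053 probes were higher and 659 lower, and the share of higher calls was 61.5 percent in place of 42.8 percent.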

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

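The tests in this part were chosen after the values were seen. Control probes of the miRNA arrays carried signal that the comparison of the regions does not use. Over 5 bright 5S rRNA probes, the log2 ratio of ameloblast over cervical loop signal, less the median of the empty spots, had a median of 0.16. Over 8 bright calibration probes it had a median of -0.54 and ranged from -1.41 to 1.10. Over 50 miRNAs above the same minimum signal of 500 it had a median of 1.18. With scaling to the 5S rRNA probes, 42 miRNAs were at least 2-fold brighter on the ameloblast array and 1 on the cervical loop array. No biological explanation was tested for the gap between these probes and the miRNAs.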

How the results depend on the processing

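The fits that join the litter block with another setting, the shares of probes that differ 2-fold in both litters, and the empty-spot, row and 5S alternatives for miRNAs were chosen after the data were seen; the others were planned. The cause of each change named here was not tested, except where the alternative removes samples or spots.

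Genotype alone gave 0 higher and 0 lower probes under the other backgrounds, scalings, filters, sources and prior variances run. The replicate block gave 197 higher and 263 lower probes. Leaving out 1 array in turn gave 0 higher probes and 0 to 10 lower ones, with 10 without mutant replicate 1 and 5 without mutant replicate 2; the lone array is then assumed to vary like the other genotype. With the block, median scaling gave 1053 higher and 659 lower probes and the deposited values gave 573 higher and 725 lower probes; the other 8 settings stayed within 1.5 times 197 and 263. All 460 blocked calls were among those with median scaling. At least 2-fold higher in both litters were 0.436 percent of tested probes, or 0.946 percent with the scanner's background, 0.721 percent with offset 16, 0.794 percent with the deposited values and 0.272 percent without the filter, which adds dim probes. At least 2-fold lower were 0.794 percent, or 1.23, 1.41 and 0.495 percent with the scanner's background, with the deposited values and without the filter. The 4 named probes kept their signs in all alternatives that gave a value.

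The 10 miRNAs at least 2-fold brighter on the ameloblast array and the 5 on the cervical loop array became 32 and 10 with the empty spots as background, 3 and 3 without correction, 0 and 52 with the 75th percentile of miRNAs detected on both arrays, 56 and 0 with that of all miRNA probes and 42 and 1 with the 5S probes. The deposited table gave 14 on the cervical loop array, and leaving out rows 1 to 16 gave 6 on the ameloblast array. With the 75th percentile of miRNAs detected on both arrays, the ratios of miR-1940 and miR-1898 turned to -0.088 and -0.20. With that of all miRNA probes, those of miR-25, miR-92a, miR-351 and miR-99b turned to 0.080, 0.031, 0.013 and 0.24. Of the other values of named miRNAs, 422 stayed within the spread of their spots and 178 moved beyond it, and of the list medians 52 stayed and 28 moved. Signs other than those after quantile normalization, most of them of ratios below 1 in size, were found for 23 of 62 named miRNAs with each of the 75th percentile scalings and for 21 with the 5S probes.

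Low signal limits the miRNA comparison, as 126 miRNAs were above background on the ameloblast array only. Not run were Dicer1, Nog, Pitx2, gene lists and seed matches (no gene for a probe), slide or scan blocks (no field names a slide or scan that holds more than 1 array) and the block with an array left out (no residual degrees of freedom). No paired analysis was possible for the miRNA arrays because each region had 1 array.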

Other observations

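The tests of explanations in this part and their bounds, the litter and crossed splits, the counts at 8-fold, and the empty-spot, 5S and row alternatives were chosen after related values had been seen, while the fits on genotype, the list medians and the other alternatives were planned. Each explanation below is a hypothesis found and tested on the same data.

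The 2 replicate numbers, taken as the litters, differed more than the 2 genotypes. Litter 2 against litter 1 gave 3741 higher and 4043 lower probes in limma with litter as the only factor, against 0 and 0 for genotype. A crossed split of the 4 arrays gave 0. Each of its groups holds both replicate numbers, so their difference enters its residual spread. Its low count therefore follows largely from the litter calls and adds no separate evidence. Over 60 repeated probes set aside as controls, above 200 intensity units, the SD of the litter difference was 0.963. It was 0.932 over the tested probes on arrays scaled only to their medians. The controls were medians of repeat spots without normexp and the tested probes single spots with it, so the 2 SDs are not alike in measure. On the replicate 1 arrays, 1108 (wild type) and 1100 (mutant) of 1260 repeated-probe spots hold other values in the deposited table. Which control a spot holds is therefore uncertain on these arrays, and this could add to the 0.963. What the controls detect is not given here, so the difference cannot be credited to the litters rather than the arrays. A trend on mean signal explained 0.0902 of the variance of the litter difference on arrays scaled only to their medians, which argues against signal-dependent labelling or scanning as the whole cause. The litter difference of neighbouring spots correlated at 0.150, too little to show uneven hybridisation and too much to exclude a part for it. A run of arrays shared by replicate number cannot be told apart from the litter, and differences in exact age, genetic background (mixed, per the labels) or dissection between litters may also contribute and were not tested.

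Large changes in the mutant incisors were mostly falls. Of the probes at least 8-fold apart in both litters, 18 were lower and 0 higher. With the deposited values 31 were lower and 1 higher, and with the scanner's own background 28 and 1. The share of lower ones was at least 96.9 percent under median scaling, cyclic loess and the deposited values, so it did not rest on the choice among these scalings. Each of them centres the arrays, while the median intensity before normalization was higher on the mutant arrays. A difference in total signal that centring removes was therefore not tested. The share was at least 96.6 percent with a smaller offset or the scanner's own background, which argues against compression of dim signals. An effect of genotype, which the design names, stays open, with 197 higher and 263 lower probes in limma with the litter as a block, and which genes these are is unknown because the probes have no gene names here.

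Of the 7 members above background of the miR-200 family and the other epithelial list, 4 (miR-200b, miR-200c, miR-203 and miR-205) were at least 2-fold brighter on the ameloblast array after quantile normalization, while the ratios of miR-200a and miR-31 were within the spread of their spots. The 3 members miR-200a, miR-200b and miR-200c have no spot in rows 1 to 16 and a median log2 ratio of 1.04, which argues against the dim upper rows as the cause for this family, although miR-429 moved from 0.93 to 0.70 without these rows and the other epithelial list had 0.65, between the bounds set for that test. The 7 members' median was at least 0.75 with the empty spots as background or without correction, which argues against background correction as the whole cause. The size of the ratios did depend on it. The miR-200 family median was 0.73 without correction and 2.40 with the empty spots, a setting that floors dim signals. The linear trend of the ratio on GC content (slope 0.020 ± 0.023 (SE) per 10 percentage points) gives the 7 members a median of at most 0.033 within its 95 percent limits, which argues against GC content. Scaling can account for the size of the ratios by the bound set for its test, since the median went from 0.076 to 1.72 over 5 scalings. That a constant factor cannot change where the members lie relative to other miRNAs holds by arithmetic and is no evidence against scaling. Less mesenchyme in the ameloblast dissection cannot be told apart from a difference between the epithelia, as the mesenchymal list's median was -0.46 and the epithelial ratios spread over 1.62, and a difference between the regions, which the design names, stays open as untested with 1 array each.

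A further hypothesis was that miRNAs with the same bases 2 to 8 differ alike between the regions, as miR-25 and miR-92a did. Over 75 same-seed pairs in 18 families, the median absolute difference of log2 ratio was 0.35 against 0.44 over all pairs. Of 10000 reshuffles of the ratios, 13.8 percent gave a median as small, so the data do not decide this. With the median of repeat spots 6.72 percent did. The median difference was 0.40 over the 49 same-seed pairs that differ at 4 or fewer bases and 0.31 over the other 26. This gap was not tested, and pairs that share a miRNA are not independent. All 9 let-7 family members were above background and share bases 2 to 8, so pairs within this family make up a large part of the 75. The log2 ratio of let-7a went from 0.96 to 0.14 without the spots of the upper rows, which were dim on the cervical loop array. These medians therefore do not decide whether more similar sequences have more similar ratios.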
